A study of Mus musculus with 4 samples.

How the data were processed

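Lung RNA of ovalbumin-sensitized and challenged BALB/cJ mice was hybridised against a pool of control lung RNA on 4 dual-colour arrays, 2 from particle-free air and 2 from UCP air. Per the labels' protocols, RNA was prepared from individual organs, 20 µg of total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5, and the reference was a pool from 6 control animals. Groups, replicate numbers and dyes were taken from the labels: the challenged lung is in Cy5 on array 1 and in Cy3 on array 2 of each air. The control pool counts as 1 control sample, and a test of the ratio against 0 leaves out the spread among controls.

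The deposited values are log2 ratios of the channels, with no scale, centring or direction stated, and the scanner, the image software and the normalization are not given in the sources used here. These were worked out from the values. On each array the largest value lay on a plateau, with 25, 44, 20 and 58 probes, which equals log2 of a ratio capped at 100000 plus 1 constant for the array (-0.05, 0.56, 0.55 and 0.28). With that constant removed, all ratios under 0.3 (381, 238, 707 and 302 values) were whole steps of a ratio rounded to 3 decimals, within 0.0011 on the log2 scale, where 28.9%, 25.5%, 31.3% and 23.7% would be by chance. The plateau was positive on the Cy5 arrays and negative on the Cy3 arrays, so the deposited values already run the same way on all 4 arrays. Scale, centring and relative direction were thereby settled, and the overall sign, challenged over control, stays likely only. Array medians were -0.01, -0.07, -0.02 and 0.02. No brightness or background values were used here, so no filter on dim probes was applied.

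Of 20205 probes, 13852 had 1 gene symbol, 0 had several and 6353 had none in the platform annotation; 13849 of the symbols were found through the Entrez identifier in the given gene table. Unnamed probes stayed in the tests by probe. Probes with a value on all 4 arrays entered the tests (18160, of which 12532 were named, for 9153 genes, 2561 of them with more than 1 probe), and 2045 probes with a missing value were left out. Values were used as deposited, with no further centring or scaling. For gene lists the probes of a gene were averaged. Probes differed by more than 1 in their averaged log2 ratio for 331 of the 2561 genes with more than 1 probe and for 22 of the 104 such members of the fixed lists. Among the genes named by rule these were Ttr, Lcn2, Coro1a, Gprc5a, Car2 and Btg2.

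Models were fitted with limma 3.58.1 (R 4.3.3): 1 coefficient per air on all 4 arrays, which leaves 2 residual degrees of freedom, moderated with eBayes (2.32 prior degrees of freedom). 4 comparisons were tested two-sided: each air against 0, their average against 0, and UCP minus particle-free air. P-values were adjusted by Benjamini-Hochberg over all probes at a threshold of 0.05. Probes at least 1.5-fold changed the same way on both arrays of an air, or on all 4, were counted without a model, beside the counts with array signs turned. A total of 27 gene lists were fixed before the data were examined, and 26 had the 5 measured genes that camera (preset correlation 0.01) required, the eosinophil list having 4. Their 104 tests were adjusted together; camera with an estimated correlation and fry stood beside them, camera with the preset correlation passed 51 combinations of list and comparison and fry passed 34. A further 11 lists (liver-made, liver-made and not raised in the acute phase, acute phase, cornified and basal squamous epithelium, fast skeletal muscle, atrial heart muscle, thymus, brown adipose, endoplasmic reticulum folding and secretion, and lysosome) were written after the values were seen and adjusted among themselves.

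Named genes followed a rule fixed in advance: up to 15 genes per direction past the threshold in the averaged effect and up to 10 in the other comparisons, the 10 with the smallest p where none passed, and up to 4 members of each list. Genes outside it (Krt13, Krt5, Prss16, Thy1, Myl3 and members of the added lists, and in the plots also Mrc1 and the liver and heart muscle transcripts that the rule does not name) were chosen after their values were seen. The fit was tested on simulated data: 18160 probes with normal errors of the moderated spread, 50 of them changed at each size. For the averaged effect it recovered 10% of the probes changed by 1 on the log2 scale and 92% of those changed by 2, with 10 false calls. For particle-free air the shares were 0% and 44% (14 false calls), for UCP air 0% and 46% (9 false calls), and for the difference 0% and 2%, reaching 72% at a change of 4 (9 false calls). The simulated errors were independent and drawn with the moderated spread, so these shares need not hold for the arrays. There, Ccl9 at 3.36 and Ccl6 at 2.28 in the averaged effect did not pass by probe. Of 20 simulated lists of 20 genes shifted by 0.5 among 9153 genes, camera with the preset correlation called 20, and 1 of 20 unshifted lists as well, and with an estimated correlation it called 0. The simulated genes varied independently, while estimated correlations within the measured lists reached 0.35. The counts for the preset correlation therefore need not hold for those lists.

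Alternatives fixed in advance were the dye orientation as a term, median centring, scaling, keeping probes with a missing value, averaging probes by gene, robust eBayes, leaving out each array, fitting each air alone, averaging the arrays of an air, and an adjusted p of 0.10; the lists were also tested by fry and with an estimated correlation. Values at the plateau treated as missing, genes of other tissues left out, and the direction markers left out of the other lists, were added after the data were seen. The genes of other tissues were those of the liver-made, acute phase, squamous, skeletal and heart muscle, thymus and fat lists. Intervals of list medians come from bootstrap draws over genes, and figures were drawn with matplotlib 3.10.9 (Python 3.11.15).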

Results

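RNA from the lungs of BALB/cJ mice, an inbred strain often used in models of allergic airway disease, was compared on 4 dual-colour arrays. Each array set lung that had been sensitized to and challenged with ovalbumin, an egg protein used as a model allergen, against a pool of lung RNA from 6 non-sensitized control animals kept in the same air. 2 arrays came from particle-free air and 2 from air carrying UCP, an abbreviation that the labels leave unexplained. In each air the challenged lung was labelled with Cy5 on array 1 and with Cy3 on array 2. The arrays held values for 19439 and 19349 probes in particle-free air and for 19832 and 19546 probes in UCP air, and 18160 probes with a value on all 4 arrays entered the tests. The number of arrays limits the precision of every value. The labels do not say whether the 2 arrays of an air hold RNA of separate animals. P-values of single probes and genes therefore measure only the spread between arrays, which may be technical. For gene lists, camera with a preset correlation compares the genes of a list with all other genes. Those p-values rest on the spread among genes and on the assumed correlation, and they measure no spread between animals.

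All values below are log2 ratios of challenged lung over its control pool. Challenged lung had been sensitized as well, while its controls were non-sensitized. Sensitization and challenge therefore cannot be told apart, and an effect of challenge below means both together. The relative direction of the 4 arrays was settled from the values, but the overall sign is only likely: it rests on the usual Cy5 over Cy3 convention and on 7 measured genes that are known to be abundant in allergic mouse lung. These 7 genes are therefore not a finding on direction. They were Chil3, Retnla, Ccl8, Arg1, Slc26a4, Itln1 and Tff2, with a median averaged log2 ratio of 3.13 (limma camera adjusted p = 6.29e-10, adjusted p = 0.218 with an estimated correlation).

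The first question was what ovalbumin challenge changed in the lung whatever the air. Chil3, Retnla, Slc26a4 and Ccl8 are among the genes used for the overall sign, so their direction is not a finding. Chil3, a chitinase-like protein of alternatively activated macrophages, rose 47.8-fold (log2 ratio 5.58 ± 0.24, SD, n = 4, limma adjusted p = 0.021) and was higher on 4 of 4 arrays. Retnla, a secreted protein of the same macrophages, had a log2 ratio of 4.53 ± 2.17 (SD, n = 4), with 1.30 on array 2 of particle-free air and at least 5.34 on the other arrays. Slc26a4, an anion exchanger of mucus-producing airway epithelium, lay at 4.24 ± 0.51, the acute phase protein Saa3 at 3.37 ± 0.60, and the chemokines Ccl9, Ccl8 and Ccl6 at 3.36 ± 0.21, 3.13 ± 0.61 and 2.28 ± 0.16 (SD, n = 4 each). On the low side, the fat-associated genes Gpd1 and Car3 lay at -2.48 ± 0.91 and -2.03 ± 0.49, and the keratin Krt13 at -2.44 ± 0.40 (SD, n = 4 each).

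**Figure D1:**
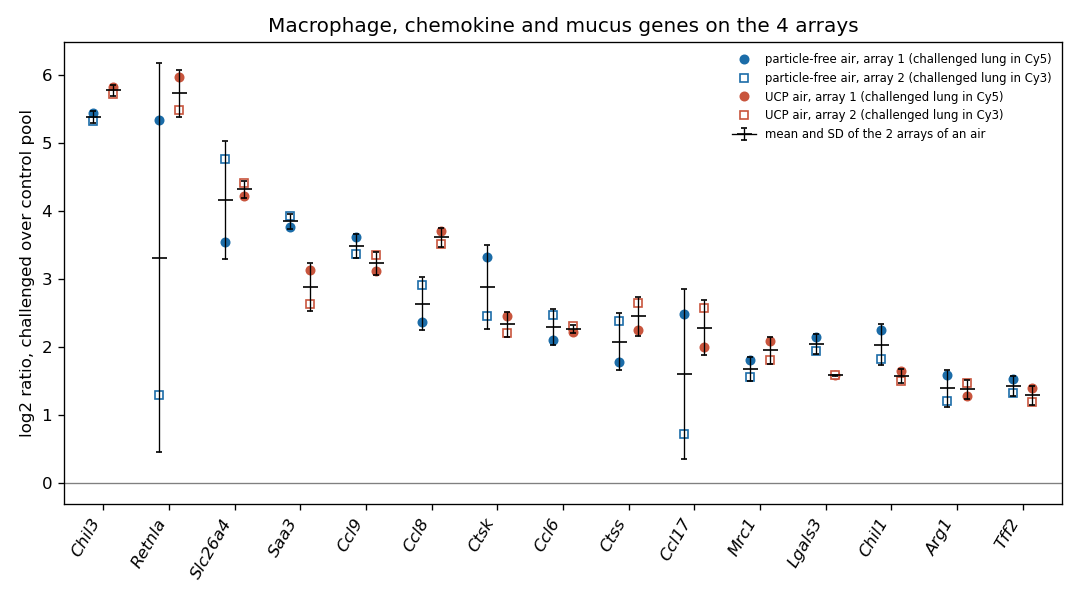
Log2 ratio of challenged lung over control pool (vertical axis) for 15 genes of macrophages, chemokines, mucus and the acute phase on the 4 arrays. Points are single arrays, and bars are the mean and SD of the 2 arrays of an air; Chil3 lies between 5.32 and 5.83 on all 4 arrays, while Retnla reaches 1.30 on array 2 of particle-free air.

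Chil3 was the only probe past the threshold of 0.05 for the averaged effect, with 0 probes on the low side. At an unadjusted p under 0.05 there were 1172 higher and 1379 lower probes, 2551 in all against 908 by chance. An adjusted p under 0.10 held 37 higher and 38 lower probes. Chil4, a near-identical gene, was not analysed here, and cross-hybridisation was not tested. With the probes of a gene averaged first, the level at which gene lists were tested, 6 genes rose (Chil3, Slc26a4, Saa3, Ccl8, Ccl6 and Ccl9) and 3 fell (Gpd1, Car3 and Nppa), with adjusted p from 0.00598 to 0.05. Among the former, Chil3, Slc26a4 and Ccl8 were used for the overall sign. Nppa, the atrial natriuretic peptide, lay at -5.81 ± 0.14 in UCP air and at 0.10 ± 0.39 in particle-free air (SD, n = 2 each). The call on Chil3 ended with the dye orientation as a term (adjusted p = 0.221), with arrays centred and scaled to the same spread (0.0801), without array 2 of UCP air (0.123) and with the 2 arrays of an air averaged into 1 value (0.317). Its log2 ratio hardly moved in these settings, from 5.58 to 5.66. Over all alternatives its adjusted p ran from 0.00598 to 0.317.

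A count that needs no estimate of the spread gave more probes. On all 4 arrays, 206 probes were at least 1.5-fold higher and 218 at least 1.5-fold lower, 424 in all, against a mean of 26 (15 to 48) when the signs of the arrays were turned in the 7 other possible ways. At 2-fold the count was 134 (62 higher and 72 lower) against a mean of 3.3. The 1.5-fold probes named 146 higher and 151 lower genes. Which direction held more probes depended on centring, with 220 higher and 203 lower once each array was centred on its median. With probes of acute phase genes and of genes made mainly in liver, squamous epithelium, muscle, heart, thymus and fat left out, 202 higher and 180 lower probes remained in the count. This setting was chosen after the data were seen.

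Gene lists fixed before the data were examined showed which groups of genes stood apart from the others. Of 26 lists tested, 12 lay above and 4 below the rest in the averaged effect by limma's camera with a preset correlation of 0.01. None of the 104 combinations of list and comparison passed with an estimated correlation, where the smallest adjusted p was 0.218. That version called 0 of 20 simulated lists shifted by 0.5, so its not passing here says little about lists with shifts of that size. Larger shifts were not simulated. Alternatively activated macrophage genes had a median log2 ratio of 1.21 (12 genes, adjusted p = 6.19e-09, adjusted p = 0.318 with an estimated correlation). Of these genes 1 passed over all genes and 9 when adjusted over the list alone. Ctsk, a lysosomal cysteine protease, and Ccl17, a chemokine that attracts type 2 helper T cells, lay at 2.61 ± 0.49 and 1.95 ± 0.85. Macrophage and monocyte genes had a median of 0.78 (25 genes, adjusted p = 5.32e-11, adjusted p = 0.218 with an estimated correlation), 0 of them past the test over all genes and 16 when adjusted over the list alone. Among them Ctss, a protease of antigen processing, lay at 2.27 ± 0.36, Lgals3 at 1.82 ± 0.28 and Gpnmb at 1.32 ± 0.17 (SD, n = 4 each).

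Genes of goblet cells and mucus had a median of 0.46 (11 genes, adjusted p = 0.000156, adjusted p = 0.269 with an estimated correlation), with Tff2, a secreted mucosal peptide, at 1.36 ± 0.14 and the airway secretory protein Bpifa1 at -0.76 ± 0.67. Neutrophil genes had a median of 0.40 (13 genes, adjusted p = 9.59e-05, adjusted p = 0.269 with an estimated correlation). Chil1 lay at 1.81 ± 0.32, and the granule proteins Ngp and Camp lay at 1.33 ± 0.35 and 1.19 ± 0.47. The 4 measured eosinophil genes were too few to test, with Alox5ap at 0.97 ± 0.32, Csf2rb2 at 0.84 ± 0.24, Prg2 at 0.49 ± 0.44 and Csf2rb at 0.27 ± 0.30. Of the chemokines and their receptors 10 lay above and 7 below 0, with a median of 0.24 (17 genes, adjusted p = 0.00243, adjusted p = 0.29 with an estimated correlation) and 6 genes higher and 0 lower when adjusted over the list alone. The 7 genes used for the overall sign make up 3 of the 11 goblet cell, 3 of the 12 alternatively activated macrophage and 1 of the 17 chemokine genes. Without them, a setting chosen after the data were seen, the medians were 0.46 (adjusted p = 0.0167), 0.64 (4.64e-05) and 0.21 (0.0169), and the goblet cell call in particle-free air ended (0.0581), where the median was 0.51 over 8 genes against 0.59 over 11. Complement and acute phase genes had a median of 0.72 (21 genes, adjusted p = 9.76e-08, adjusted p = 0.292 with an estimated correlation), with Saa3 and Hpx highest among them. The airs were unequal, with a median of 0.78 in particle-free air and 0.33 in UCP air. Hpx lay at 3.83 and 3.50 on the arrays of particle-free air and at 1.20 and 0.48 on those of UCP air.

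Antigen presentation genes had a median of 0.52 (16 genes, adjusted p = 0.000108, adjusted p = 0.305 with an estimated correlation), with the invariant chain Cd74 at 0.91 ± 0.31 and the class II gene H2-Ab1 at 0.87 ± 0.42. Cell cycle genes had a median of 0.41 (33 genes, adjusted p = 1.39e-07, adjusted p = 0.239 with an estimated correlation), 28 of them above 0 and 10 past the test when adjusted over the list alone. Cks1b, a partner of cyclin-dependent kinases, lay at 1.44 ± 0.38 and Cdc20 at 0.93 ± 0.32. B cell and plasma cell genes had a median of 0.36 (11 genes, adjusted p = 0.0215, adjusted p = 0.454 with an estimated correlation), with the B cell coactivator Pou2af1 at 1.31 ± 0.48. Interferon response genes had a median of 0.31 (17 genes, adjusted p = 0.00952, adjusted p = 0.504 with an estimated correlation) and 0 members past the test when adjusted over the list alone. Extracellular matrix and protease genes had a median of 0.17 (33 genes, adjusted p = 0.00208, adjusted p = 0.374 with an estimated correlation). In this list 11 genes were higher and 2 lower when adjusted over the list alone, among them Col3a1 at 1.60 ± 0.47 and Dcn at -1.07 ± 0.42.

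On the low side, adipose genes had a median of -0.87 (12 genes, all below 0, adjusted p = 9.9e-10, adjusted p = 0.218 with an estimated correlation), and 2 of them fell in the test over all genes. Heart and striated muscle genes had a median of -0.79 (29 genes, adjusted p = 2.06e-12, adjusted p = 0.218 with an estimated correlation), with -0.03 in particle-free air and -1.41 in UCP air. Alveolar type 2 and surfactant genes had a median of -0.23 (13 genes, adjusted p = 0.0265, adjusted p = 0.353 with an estimated correlation), with the surfactant protein Sftpb at -0.88 ± 0.25. Smooth muscle genes had a median of -0.19 (12 genes, adjusted p = 0.0216, adjusted p = 0.327 with an estimated correlation), with Myh11, the smooth muscle myosin, at -0.98 ± 0.19.

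The other lists did not pass in the averaged effect. Oxidative stress and xenobiotic genes had a median of 0.09 (29 genes, adjusted p = 0.729), with Gpx1, which removes hydrogen peroxide, at 1.16 ± 0.11 and the conjugating enzyme Gstm1 at -0.99 ± 0.23. Airway club and ciliated cell genes had a median of -0.02 (20 genes, adjusted p = 0.439), with the club cell enzymes Cyp2f2 and Cyp4b1 at -1.29 ± 0.39 and -0.99 ± 0.23. Endothelium and alveolar type 1 genes had a median of -0.07 (19 genes, adjusted p = 0.451), mast cell and basophil genes of 0.04 (6 genes, adjusted p = 0.611), T cell genes of -0.19 (18 genes, adjusted p = 0.0759) and blood red cell genes of -0.27 (7 genes, adjusted p = 0.0929). Immediate early and heat shock genes had a median of 0.14 (27 genes, adjusted p = 0.272), circadian clock genes of 0.01 (8 genes, adjusted p = 0.605), glucocorticoid responsive genes of -0.12 (10 genes, adjusted p = 0.949) and housekeeping genes of 0.47 (11 genes, adjusted p = 0.0527, adjusted p = 0.011 by fry). The housekeeping list was meant as a control, with 7 genes above and 4 below 0 and a mean of 0.24. Its median was about as high as that of lists that passed, such as goblet cell and mucus genes (0.46) and neutrophil genes (0.40). List medians of this size are therefore not clearly apart from that of the control list. Among these 104 combinations, median, mean and test differed in sign only where the list did not pass, as for the glucocorticoid responsive genes with their mean of 0.11.

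The next question was what challenge changed in particle-free air. Chil3 lay at 5.38 ± 0.09, Saa3 at 3.85 ± 0.11 and Ccl9 at 3.49 ± 0.18 (SD, n = 2 each). The other 7 of the 10 genes with the smallest p encode plasma proteins that the liver makes: Alb (albumin) at 4.61 ± 0.20, Ttr at 3.89 ± 0.53, the heme carrier Hpx at 3.66 ± 0.24, the antiproteases Serpina1e, Serpina1d and Serpina1b at 3.48 ± 0.04, 3.32 ± 0.26 and 3.21 ± 0.49, and Apoh at 2.97 ± 0.03. The 2 Ttr probes disagreed, with averaged log2 ratios of -0.26 and 2.60. A list of liver-made genes, written after these values were seen, had a median of 0.87 in particle-free air (51 genes, adjusted p = 2.67e-18, adjusted p = 0.11 with an estimated correlation) and of 0.08 in UCP air (adjusted p = 0.436). Its 30 genes not seen before had a median of 0.60 in particle-free air. The p-value there rests in part on genes seen before the list was written.

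In particle-free air limma called 0 probes (smallest adjusted p = 0.109, for Chil3), with 826 higher and 1069 lower at an unadjusted p under 0.05 against 908 expected in all. At least 1.5-fold on both arrays, 668 probes were higher and 839 lower, against 981 that followed the dye. With each array centred on its median the balance turned, to 783 higher and 746 lower. Averaging the probes of a gene first gave 1 call (Chil3, adjusted p = 0.0316). Of the fixed lists 12 lay above and 3 below the others. Complement and acute phase genes had a median of 0.78 (adjusted p = 6.66e-10, adjusted p = 0.271 with an estimated correlation), a list that holds Hpx and Saa1 (2.66 ± 0.51) as well as Saa3. Housekeeping genes, meant as a control, lay higher too, with a median of 0.32 (11 genes, adjusted p = 0.0121, adjusted p = 0.318 with an estimated correlation).

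The same question was put to UCP air. Chil3 lay at 5.78 ± 0.08, Ccl8 at 3.61 ± 0.14 and Ccl9 at 3.23 ± 0.17, beside 2.64 ± 0.39 for Ccl8 and 3.49 ± 0.18 for Ccl9 in particle-free air, while Nppa lay at -5.81 ± 0.14, a 56.2-fold lower level (SD, n = 2 each). Myl4 and Myl7, the atrial myosin light chains, lay at -2.74 ± 0.04 and -2.83 ± 0.24, and Gpd1 at -2.91 ± 0.25 on its probe with the smallest p. The others of the 10 genes with the smallest p were Ctxn1 at 3.86 ± 0.03, Emx1 at 3.64 ± 0.52 and Supt20 at -4.01 ± 0.28. Heart and striated muscle genes had a median of -1.41 (29 genes, 25 below 0, adjusted p = 2.56e-21, adjusted p = 0.218 with an estimated correlation). In this list 1 gene passed over all genes (Nppa, adjusted p = 0.0282) and 23 were lower when adjusted over the list alone.

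In UCP air limma called 0 probes (smallest adjusted p = 0.0808, for Chil3), with 672 higher and 863 lower at an unadjusted p under 0.05 against 908 expected in all. Averaging the probes of a gene first gave 2 calls, Chil3 and Nppa. At least 1.5-fold on both arrays, 587 probes were higher and 826 lower, against 454 that followed the dye. Of the fixed lists 12 lay above and 4 below the others. T cell genes had a median of -0.34 (18 genes, adjusted p = 0.0023, adjusted p = 0.337 with an estimated correlation), with the coreceptor Cd8a at -1.58 ± 0.03 and Thy1 at -1.28 ± 0.01. Thymus genes, a list written after the data were seen that holds Cd8a and Thy1 too, had a median of -0.75 in the same arrays (19 genes, adjusted p = 1.29e-09, adjusted p = 0.11 with an estimated correlation), with the thymic protease Prss16 at -2.25 ± 0.94. With the genes of other tissues left out, a setting chosen after the data were seen, the T cell call in UCP air ended and its direction turned (10 of 18 genes left, adjusted p = 0.995). That setting takes the thymus list's genes, Cd8a and Thy1 among them, out of the T cell list. The lost call therefore cannot tell thymus tissue from T cells.

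**Figure D2:**
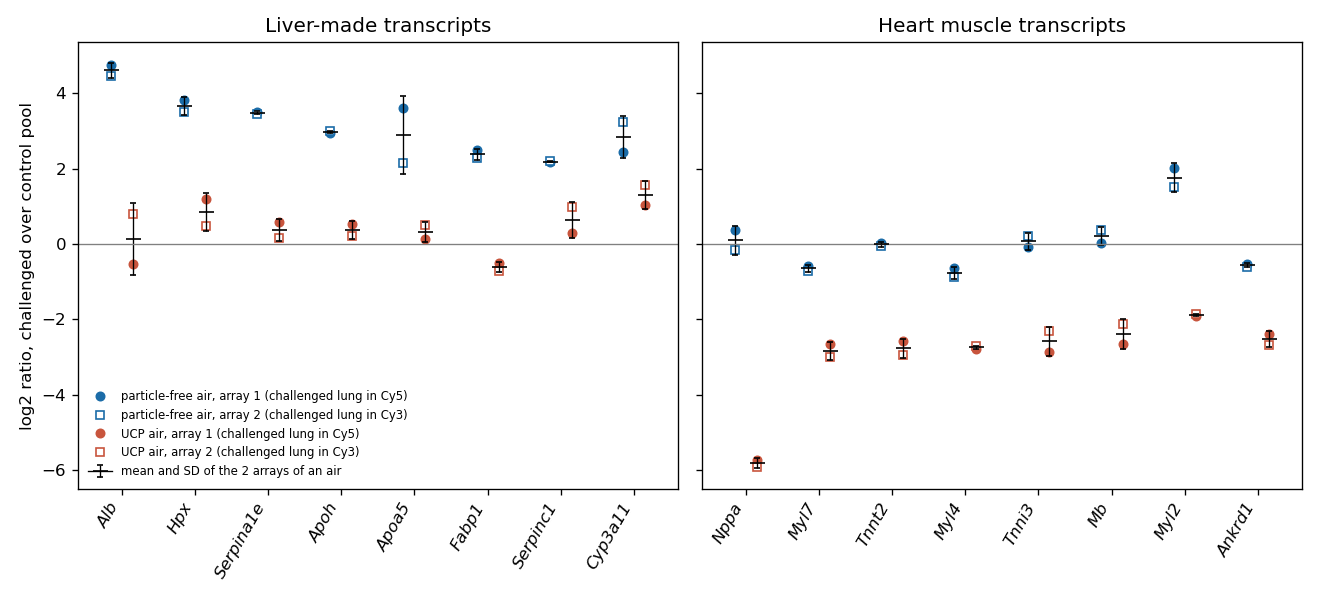
Log2 ratio of challenged lung over control pool (vertical axis, shared) for 8 liver-made transcripts (left) and 8 heart muscle transcripts (right) on the 4 arrays. Points are single arrays, and bars are the mean and SD of the 2 arrays of an air; Alb lies at 4.75 and 4.46 in particle-free air and at -0.53 and 0.81 in UCP air, and Nppa at -5.72 and -5.91 in UCP air.

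The last comparison asked whether the effect of challenge differed between the airs. Of the 10 genes with the smallest p, 4 encode heart muscle proteins and 2 liver proteins. UCP minus particle-free, the log2 difference was -5.92 for Nppa, -3.65 for the ventricular light chain Myl2, -2.75 for Tnnt2, -2.69 for the fatty acid carrier Fabp3, -3.10 for Serpina1e and -2.99 for Fabp1, the liver's fatty acid carrier. Part of the Myl2 difference came from particle-free air, where Myl2 lay at 1.77 ± 0.37 and its relative Myl3 at 0.68 ± 0.55 (SD, n = 2 each). Ctxn1 and Emx1 differed by 4.04 and 3.52, and Supt20 and Mtmr6 by -4.05 and -2.92. None of them passed the test, where the smallest adjusted p was 0.69 (Nppa). limma called 0 probes, and 355 higher and 367 lower probes at an unadjusted p under 0.05 made 722 against 908 expected by chance. The airs have different control pools, so each difference compares ratios, not levels.

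Of the fixed lists 4 lay lower in UCP air and 0 higher. Heart and striated muscle genes differed by a median of -1.35 (29 genes, adjusted p = 2.93e-20, adjusted p = 0.218 with an estimated correlation), and adipose genes by -0.81 (12 genes, adjusted p = 0.0011, adjusted p = 0.287 with an estimated correlation). T cell genes differed by -0.54 (18 genes, adjusted p = 0.000662, adjusted p = 0.318 with an estimated correlation). Complement and acute phase genes differed by -0.50 (21 genes, adjusted p = 0.000162, adjusted p = 0.337 with an estimated correlation). With the genes of other tissues left out, the T cell difference (10 genes left, adjusted p = 0.408) and the complement and acute phase difference (13 genes left, adjusted p = 0.132) no longer passed. That setting takes thymus genes out of the former list, and acute phase and liver-made genes out of the latter. The lost calls therefore do not show another tissue as the source. Medians of the genes left are not given here, so a smaller difference cannot be told from fewer genes. For the macrophage and monocyte list the median difference was 0.04 (adjusted p = 0.605), for the alternatively activated macrophage list 0.03 (adjusted p = 0.878), for goblet cell and mucus genes 0.16 (adjusted p = 0.512) and for oxidative stress and xenobiotic genes -0.07 (adjusted p = 0.409). The probes at least 1.5-fold higher on both arrays of each air overlapped in 206, against 21.6 for independent lists, and the lower ones in 218, against 38.2. Opposite directions overlapped in 13 and 10 probes, against 30.4 and 27.1.

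Across probes, which are not independent replicates, the 2 arrays of an air correlated weakly, with Pearson's r of 0.07 in particle-free air and 0.16 in UCP air. Plateau values were kept in r. Spearman's rho, which uses ranks, was 0.12 in particle-free air and 0.26 in UCP air. Between airs, r was 0.18 and 0.12 for arrays of the same dye orientation and 0.07 and 0.12 for arrays of opposite orientation.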

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

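All tests of an explanation in this part, and the lists of liver, muscle, squamous and thymus genes, were chosen after the values were seen. 4 fixed lists differed between the airs in a test of the difference itself, UCP minus particle-free: heart and striated muscle genes by a median log2 of -1.35 (adjusted p = 2.93e-20, adjusted p = 0.218 with an estimated correlation) and adipose genes by -0.81 (adjusted p = 0.0011, adjusted p = 0.287 with an estimated correlation). T cell genes differed by -0.54 (adjusted p = 0.000662, adjusted p = 0.318 with an estimated correlation). Complement and acute phase genes differed by -0.50 (adjusted p = 0.000162, adjusted p = 0.337 with an estimated correlation). With genes of other tissues left out, the T cell difference (10 of 18 genes left, adjusted p = 0.408) and the complement and acute phase difference (13 of 21 left, adjusted p = 0.132) no longer passed. The genes taken out include thymus and acute phase genes of these lists, and medians of the rest are not given. The lost calls therefore do not show another tissue as the source. By limma's fry only the heart and striated muscle difference passed among these 4 (adjusted p = 0.011), with 0.0538 for adipose, 0.093 for T cell and 0.15 for complement and acute phase genes.

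Transcripts made in the liver were higher in particle-free air, and 8 of the 51 genes of that list are also held by fixed lists. Among 29 liver-made genes that the acute phase does not raise, the median log2 ratio in particle-free air was 1.04 (bootstrap interval 0.68 to 1.65; 0.69 over the 21 not seen before), with Alb at 4.61, as liver tissue or liver RNA in the challenged particle-free sample would give. An acute phase response of the lung with no liver RNA would leave these genes near 0. The lower bound of their median was 0.68 over all 29, those seen before included, and the 21 others have no interval. Such intervals are drawn over genes and measure no spread between animals. Dye bias of equal size on both dye orientations cancels in their mean, where the liver-made list lay at 0.87 (0.62 to 1.40). Its 30 genes not seen before had a median of 0.60, and 70% of them had the same sign on both orientations (exact 95% interval 50.6 to 85.27%). Liver material therefore stays a candidate source, as a hypothesis, beside a biological difference between the airs that was not tested.

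Heart muscle transcripts were lower in UCP air, with a median of -1.41 over 29 genes (bootstrap interval -1.82 to -0.98) and Nppa, abundant in the atrium, at -5.81, as heart tissue in the UCP control pool would give. Skeletal muscle genes were lower in both airs (-0.88 and -0.64), but skeletal muscle in that pool alone would lower them further in UCP air, and their median difference was 0.14 (-0.31 to 0.48). A fall of heart muscle transcripts with challenge whatever the air would show in particle-free air, where the median was -0.03 (-0.56 to 0.07). A list of 6 atrial genes was lower there too (-0.48, adjusted p = 0.0395, adjusted p = 0.21 with an estimated correlation), so a smaller fall of these in both airs stays open. Heart tissue in the pool stays a candidate source, as a hypothesis, though it would not raise Myl2 in particle-free air (1.77), and an effect of UCP on the heart muscle of lung veins was not tested.

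Squamous and skeletal muscle transcripts were lower in the averaged effect. Cornified squamous genes had a median averaged log2 ratio of -0.84 (24 genes; bootstrap interval -1.58 to -0.21; -0.16 over the 12 not seen before) and fast skeletal muscle genes of -0.78, which leaves open whether tissue next to the lung entered both control pools, since the interval reaches -0.21. Dilution of resident lung cells by incoming cells cannot be told apart from it on the first test made: the resident lists lay 0.70 above the cornified list, but the interval of 0.09 to 1.52 reaches below the bound of 0.3. With skeletal muscle genes pooled in, tried only after that result, the gap was 0.68 (0.39 to 1.07), and over genes not seen before 0.29 (0.02 to 0.58), so it rests in part on genes picked for being low. Dye bias of equal size on both orientations would cancel and leave 0 in place of -0.84, one of unequal size was not tested, and 33.33% of the 12 cornified genes not seen before had the same sign on both orientations within both airs, where chance gives 25% (exact 95% interval 9.92 to 65.11%).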

How the results depend on the processing

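The settings with plateau values as missing or with other tissues' genes or the direction markers left out were chosen after the data were seen. Counts of called probes were small and moved. Replicate numbers, which are the dye orientations, did not pair the arrays by any label, and the correlation of replicate 1 minus replicate 2 between airs was 0.05 (Spearman's rho 0.12). With them as a replicate block the averaged effect had 0 calls. It had 2 with arrays scaled, 9 with probes of a gene averaged first, 0 with the arrays of an air averaged, 75 at an adjusted p of 0.10, and 22, 9, 34 and 0 without array 1 or 2 of particle-free air or array 1 or 2 of UCP air, in that order. Particle-free air had 10 calls with missing values kept, 1 with probes averaged by gene and 24, 8, 0 and 0 without each array. UCP air had 2 by gene and 0, 0, 36 and 4 without each array. The difference had 19, 8, 32 and 0 without each array. A lone array of an air was there assumed to vary like the other air's, and it carries the dye effect with it. The same-direction counts fell by construction at 2-fold to 418, 449 and 134, and counts over all arrays rose to 696, 636, 664 and 609 without each array, since fewer arrays must pass. Same-direction probes were more often higher than lower with centring (783 and 746 in particle-free air, 220 and 203 over all arrays) and scaling (645 and 623, 214 and 192), unlike in UCP air (581 and 831 centred, 703 and 959 scaled). Spearman's rho was 0.12 and 0.26 within airs and 0.28, 0.17, 0.20 and 0.30 between them. With an estimated correlation 0 lists passed in every comparison; fry passed 9 in UCP air and 2 in the difference, heart and striated muscle and housekeeping genes. Its new calls were housekeeping genes in UCP air and averaged (adjusted p = 0.011 each) and in the difference (0.0422). Centring kept 51 of 51 list calls, the replicate block 49, fry 31, leaving out arrays 41 to 48, leaving out other tissues' genes 48 and leaving out the direction markers 50. Turning all signs gave -3.13 for the direction markers. Among 128 named results, 867 repeats kept direction and side of the threshold, 50 lost their call, 4 gained it and 3 uncalled values changed sign without 1 array, with ranges of -0.04 to 0.21 for Tpsb2, -0.58 to 2.93 for Spa17 and -0.94 to 0.00 for Klf9. Where no cause follows from the setting, the cause was not tested. Signal over background was not used here.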

Other observations

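The groups in this paragraph were written after the values were seen. Genes of protein folding and secretion in the endoplasmic reticulum had a median averaged log2 ratio of 0.48 (45 genes, 39 above 0, adjusted p = 2.08e-09, adjusted p = 0.11 with an estimated correlation), and 13 of them were higher when adjusted over the list alone. Among them the translocation channel subunit Sec61b lay at 1.36 ± 0.34, the peroxiredoxin Prdx4 at 1.14 ± 0.12, Creld2 at 1.05 ± 0.13 and the chaperone Hspa5 at 0.76 ± 0.19 (SD, n = 4 each). Lysosomal genes had a median of 0.37 (44 genes, adjusted p = 3.65e-08, adjusted p = 0.11 with an estimated correlation), 9 of them also in fixed lists. Psap, the precursor of the saposins, lay at 1.44 ± 0.19, the tetraspanin Cd63 at 1.27 ± 0.26 and Hexa at 1.09 ± 0.17 (SD, n = 4 each). Between airs these lists differed by medians of -0.01 (adjusted p = 0.524) and 0.00 (adjusted p = 0.822). The housekeeping list, meant as a control, had a median averaged log2 ratio of 0.47. The medians of the folding and lysosomal lists are therefore not clearly apart from that of the control list.

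Other lists written after the values were seen are given as values. Where such a list holds genes already seen, its p-value is no separate test. Cornified squamous genes had an adjusted p of 2.08e-09 in the averaged effect (adjusted p = 0.11 with an estimated correlation) and fast skeletal muscle genes of 1.09e-11 (adjusted p = 0.119 with an estimated correlation). The 12 cornified genes not seen before had a median of -0.16, against -0.84 over all 24. The cornified p-value therefore rests in part on genes picked for being low. Liver-made genes that the acute phase does not raise had an adjusted p of 2.35e-14 in particle-free air (adjusted p = 0.11 with an estimated correlation). Their median there was 1.04 over all 29 and 0.69 over the 21 not seen before. Liver-made genes differed between airs by a median of -1.05 (adjusted p = 3.57e-20, adjusted p = 0.11 with an estimated correlation), acute phase genes by -1.05 (adjusted p = 3.45e-09, adjusted p = 0.14 with an estimated correlation), thymus genes by -0.58 (adjusted p = 2.77e-06, adjusted p = 0.11 with an estimated correlation), brown adipose genes by -0.59 (adjusted p = 0.00101, adjusted p = 0.125 with an estimated correlation) and atrial heart muscle genes by -1.31 (adjusted p = 1.2e-05, adjusted p = 0.11 with an estimated correlation). Basal squamous genes had a median averaged log2 ratio of -0.28 (9 genes, adjusted p = 0.016, adjusted p = 0.429 with an estimated correlation), with Krt5 at -2.24 ± 0.98 (SD, n = 4). Ucp1, the uncoupling protein of brown fat, lay at -0.61 ± 0.01 in particle-free air and -2.80 ± 0.75 in UCP air (SD, n = 2 each).

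Supt20 lay at -4.01 in UCP air, next to Nppa at -5.81, and their probe numbers are 2 apart. Over 16609 pairs of probes that are 2 numbers apart, the log2 ratios in UCP air correlated with r = 0.03, across probes that are not independent. Coro1a's highest value, 5.88, came from array 1 of particle-free air, as a mean over 3 probes that disagreed. In that air the T cell list had a median of -0.07 and a mean of 0.18.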
